A study of Drosophila melanogaster with 34 samples.

How the data were processed

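The labels list 34 samples: 12 embryo messenger RNA libraries and 22 small RNA samples of sperm, seminal vesicle and testis. Per the labels' protocols, small RNA libraries were made with the NEBNext Small RNA kit after blocking 2S rRNA, PIWI IP samples were immunoprecipitated from dissected tissue after UV crosslinking, and testis libraries were made in a smaller volume than sperm libraries. The labels give the small RNA protocol for the embryo samples as well, so the embryo library protocol and the embryo stage are not known here. The embryo titles name total RNA, and the embryo column names begin with the word Old, whose meaning is not given. Samples were prepared at different sites, which the labels do not give per sample. The libraries carried no stated molecular identifiers, so intervals and floors cover counting error only.

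The authors deposited the counts used here: 1 table of gene counts for the embryos (13931 rows) and a sense table (46612 rows) and an antisense table (37771 rows) of counts per feature for the small RNA. The submitters' processing notes name Trim Galore 0.5.0, cutadapt, Bowtie 1.2.3, SAMtools 1.8, featureCounts, Subread 2.0.0 and the builds dm6 and BDGP6, without saying which served which table. The handling of reads with more than 1 position and the use of strand for the embryo table are not stated. Rows that share reads with near-identical copies (transposable elements, Stellate and its suppressor, tRNA, snoRNA and miRNA clusters, histones, the Prx2540 genes) are therefore uncertain as single rows. The values were checked to be whole numbers per table; the seminal vesicle columns and the other small RNA columns were counted on different feature lists, and only features in the list of a comparison were used.

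Columns were matched to samples by name. The third seminal vesicle total RNA sample has no column, so the comparison planned with 7 libraries used 6, and each testis group of 2 labelled samples has 1 usable column. A further 3 columns in each of the small RNA tables matched no sample and were not used. The column names of the embryo table mark a batch 2 (2 paternal aub, 2 WT and both maternal aub libraries); the remaining 6 are called batch 1 here. No library was a copy of another: replicate pairs differed by more than counting error (lowest mean chi-square 4.13).

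Assigned counts per library were 1690431 to 16289732 for embryos, 2325192 to 18515091 for small RNA sense and 22842 to 330029 for small RNA antisense. A limit of 3 counts corresponds to 0.168 to 1.68 CPM in embryo libraries, 0.277 to 0.810 in sperm, 0.102 to 0.606 in seminal vesicle, and 0.345 to 0.817 in the sperm and testis set. The features with the most small RNA counts were LSU-rRNA (54.0%), SSU-rRNA (22.0%), cluster92 (1.87%), 5.8SrRNA-Psi:CR45863 (1.60%) and mir-1 (1.57%).

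Counts were tested in R 4.3.3 with edgeR 4.0.16 (filterByExpr, TMM factors, robust quasi-likelihood F test, Benjamini-Hochberg adjustment, threshold 0.05). Sense and antisense rows entered 1 fit. Embryo and sperm fits held all 3 groups each, which share 1 estimate of the spread. CPM of single rows used TMM-scaled library sizes, and summed CPM of lists used total counts. Standard errors were the absolute log2 fold change divided by the square root of F. The sperm and testis fit set 3 WT sperm libraries against the mean of T1, T2 and T3 with the spread of sperm alone, so each lone testis library is assumed to vary as sperm does. The testis comparisons T2 against T1, T3 against T1 and T3 against T2, planned with 2 libraries each, could not be tested and are given as values with counting intervals. Because libraries of a group may be aliquots or pools, which the labels do not state, p values may measure only technical spread.

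Gene lists with at least 5 tested members were tested with camera in limma 3.58.1 (preset correlation 0.01, and again with an estimated correlation) and with fry. The embryo lists were early zygotic, maternal transcripts degraded early, piRNA pathway, heterochromatin proteins, Polycomb group, glycolysis, TCA cycle, oxidative phosphorylation, mitochondrially encoded, lipid metabolism, sugar sensing and insulin signalling, cytosolic ribosomal proteins, heat shock and stress, innate immunity, dosage compensation and sex determination, replication-dependent histones, follicle cell and eggshell, sperm and testis, late embryo and larval tissues, and germ plasm and pole cells. A transposable element list for embryos had 0 members in the table. The small RNA lists were miRNA, tRNA and snoRNA genes, transposable elements, telomeric elements, gypsy-clade elements, germline elements, Stellate and its suppressor, genic piRNA sources, endo-siRNA hairpins, testis-enriched and broadly expressed miRNAs, accessory gland and seminal vesicle genes, sperm and testis transcripts, and Y-linked fertility genes. Telomeric elements had 3 or 4 tested rows per strand, and Stellate sense and the Y-linked genes 1 row each in sperm, so these were not tested there. A row was also called adjusted over the list alone, with the Benjamini-Hochberg method among the list's members. Shares of counts in sperm were compared with exact permutation tests over 27 shares, and shares of single libraries are given with 95% Clopper-Pearson intervals.

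Genes named in the text were chosen by a rule. It names aub and piwi. It further names rows with an adjusted p under 0.05, non-overlapping libraries and a mean of at least 5 CPM (messenger RNA) or 20 CPM (small RNA): the 8 largest changes in each direction for embryos, and per strand the 4 largest in the mutant sperm and vesicle comparisons and the 3 largest in the sperm and testis comparison. Names with only a CG or CR number were skipped while 3 others remained. It also names up to 4 members of each list with the smallest p, and, where fewer than 3 rows pass, the 5 rows with the smallest p. The text gives a part of the genes so named, chosen after their values were seen, and marks genes outside the rule. The groups, comparisons, tests, gene lists and this rule were fixed before the data were examined.

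Alternatives fixed before the data were examined were DESeq2 size factors, the DESeq2 1.42.0 Wald test, no filter, a replicate block, each library left out in turn, fits of the compared groups only, an early zygotic covariate, scaling by library size or by miRNA counts, strands fitted apart, shares without the 5 largest features, and an estimated correlation for the lists. Chosen after seeing the data were a batch term, fits within each batch, a maternal transcript covariate, rRNA rows left out, and testis as 1 group. On simulated data with changes of 2, 4 and 8-fold, the embryo fit recovered 22.4%, 88.1% and 92.4% of changed genes with 3 false among 138 calls. The aub sperm fit recovered 10.4%, 83.6% and 90.9% (15 of 138 false), the vesicle fit 1.49%, 64.2% and 92.4% (16 of 121) and the sperm and testis fit 4.48%, 55.2% and 83.3% (16 of 111), and in each the list tests found the changed list. Most 2-fold changes were thus missed, and none between 2 and 4-fold were simulated. Changed rows were drawn only from those at or above the median level, with rows independent and no batch or stage difference. Recovery of lower rows, or under such differences, is therefore not known. In the aub sperm, vesicle and sperm and testis fits, false calls were a larger share than the adjusted p threshold allows on average. Positions are those of the reference annotation of assembly Release 6 plus ISO1 MT.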

Results

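Messenger RNA of Drosophila melanogaster embryos and small RNA of sperm, testis and seminal vesicle were measured in 34 samples. The 12 embryo libraries fell into 5 whose father carried mutant aubergine (aub), 2 whose mother did, and 5 wild type (WT). The aub and piwi genes encode PIWI-clade Argonaute proteins, which bind the small RNAs called piRNAs. The 22 small RNA samples comprised 3 sperm libraries each of WT, piwi mutant and aub mutant males, 4 PIWI immunoprecipitates (IP) and 3 total RNA samples of seminal vesicle, and 6 WT testis samples in the groups T1, T2 and T3. The tables held columns for 2 of the seminal vesicle total RNA samples and for 1 testis library per group. Embryo libraries held 4634192 to 16289732 assigned counts in the paternal aub group, 4147539 to 12274261 in the maternal aub group and 1690431 to 8816293 in WT. Small RNA libraries held 2325192 to 18515091 sense counts and 22842 to 330029 antisense counts.

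The aub and piwi transcripts were examined first in embryos, as a check of the labels. In CPM (counts scaled by library size), aub measured 7.06 ± 4.68 (SD, n = 5) in paternal aub, 4.51 ± 2.97 (n = 2) in maternal aub and 19.8 ± 19.9 (n = 5) in WT embryos. Single libraries lay at 3.95, 4.22, 4.92, 7.08 and 15.1 CPM in paternal aub, at 2.41 and 6.61 in maternal aub, and from 4.49 to 53.5 in WT. The piwi transcript measured 9.97 ± 4.35, 10.7 ± 0.645 and 30.8 ± 32.0 CPM in the same groups. Neither gene passed the test: the log2 fold change of aub against WT was -1.46 ± 0.65 (SE) in paternal aub (edgeR, adjusted p = 0.202) and -2.09 ± 0.95 in maternal aub (0.527). For piwi it was -1.62 ± 0.60 (0.155) and -1.52 ± 0.85 (0.527). The sign depended on the batch that the column names gave, since paternal aub against WT gave -2.78 for aub and -2.66 for piwi in batch 1 (paternal 1 to 3, WT 1 to 3) and 1.18 and 0.63 in batch 2 (2 libraries of each group). The transcript levels thus did not separate the genotypes, and the embryos' own aub genotype was not given. In sperm, the aub and piwi small RNA rows fell below the count filter, so they did not check the sperm labels.

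The first comparison asked whether a father's aub mutation changes gene expression in the embryo. The transcript of mthl8 (methuselah-like 8, FBgn0052475; 3L, 22428 to 26308) rose from 0 counts in all 5 WT libraries to 14.3 ± 2.12 CPM in the 5 paternal aub libraries, at least 17.2-fold with a limit of 3 counts per WT library (edgeR quasi-likelihood test, adjusted p = 2.5e-04). GILT3 (3R, 23677358 to 23678421) rose from 2.20 ± 0.811 to 11.4 ± 2.67 CPM, a log2 fold change of 2.33 ± 0.32 (adjusted p = 0.0255). CG42825 rose from 1.50 (range 0.997 to 2.22) to 16.7 ± 9.98 CPM (3.42 ± 0.48, 0.0258), and CG4835 (3L, 5479790 to 5483663) from 10.9 ± 3.70 to 47.4 ± 18.1 CPM (2.13 ± 0.32, 0.0365). CG18417 (3L, 7400070 to 7401671), chosen after its values were seen, rose from 0.237 ± 0.139 to 4.25 ± 1.28 CPM (3.91 ± 0.45, 0.00588). Its WT level rests on 7 counts in 5 libraries, so the size of this rise is uncertain. The 1 gene that fell was neo (3R, 29819131 to 29825800), from 25.8 ± 9.90 to 5.37 ± 1.88 CPM (-2.26 ± 0.35, 0.0436). Of 10371 genes tested, 5 rose and 1 fell, 2444 had an unadjusted p under the same threshold, and DESeq2 called 883 (234 up, 649 down). This fit held no batch term. A batch term, chosen after seeing the data, gave 33 calls (23 up, 10 down). Leaving out WT 2-batch2 gave 734 calls (111 up, 623 down) and leaving out WT 1-batch2 gave 228 (21 up, 207 down). Both groups' values did not overlap in 1.96% of genes.

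All 6 genes had the same sign in each batch. In batch 2 alone, mthl8 (0 counts in WT), GILT3 (2.08), CG4835 (1.22) and CG18417 (4.47) passed the threshold, while CG42825 (2.32, adjusted p = 0.0547) and neo (-1.53, 0.0547) did not. Calls of mthl8 and CG18417 held without any single library. That of GILT3 was lost without paternal 1, paternal 2, WT 2 or WT 3 (log2 fold change 2.20 to 2.53), and that of CG42825 without paternal 1, 2 or 3 or WT 1, 2 or 3 (3.12 to 3.65). CG4835 lost its call without the same 6 libraries or paternal 1-batch2 (1.95 to 2.30), and neo lost it without 8 of the 10 libraries (-2.42 to -2.08).

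**Figure D1:**
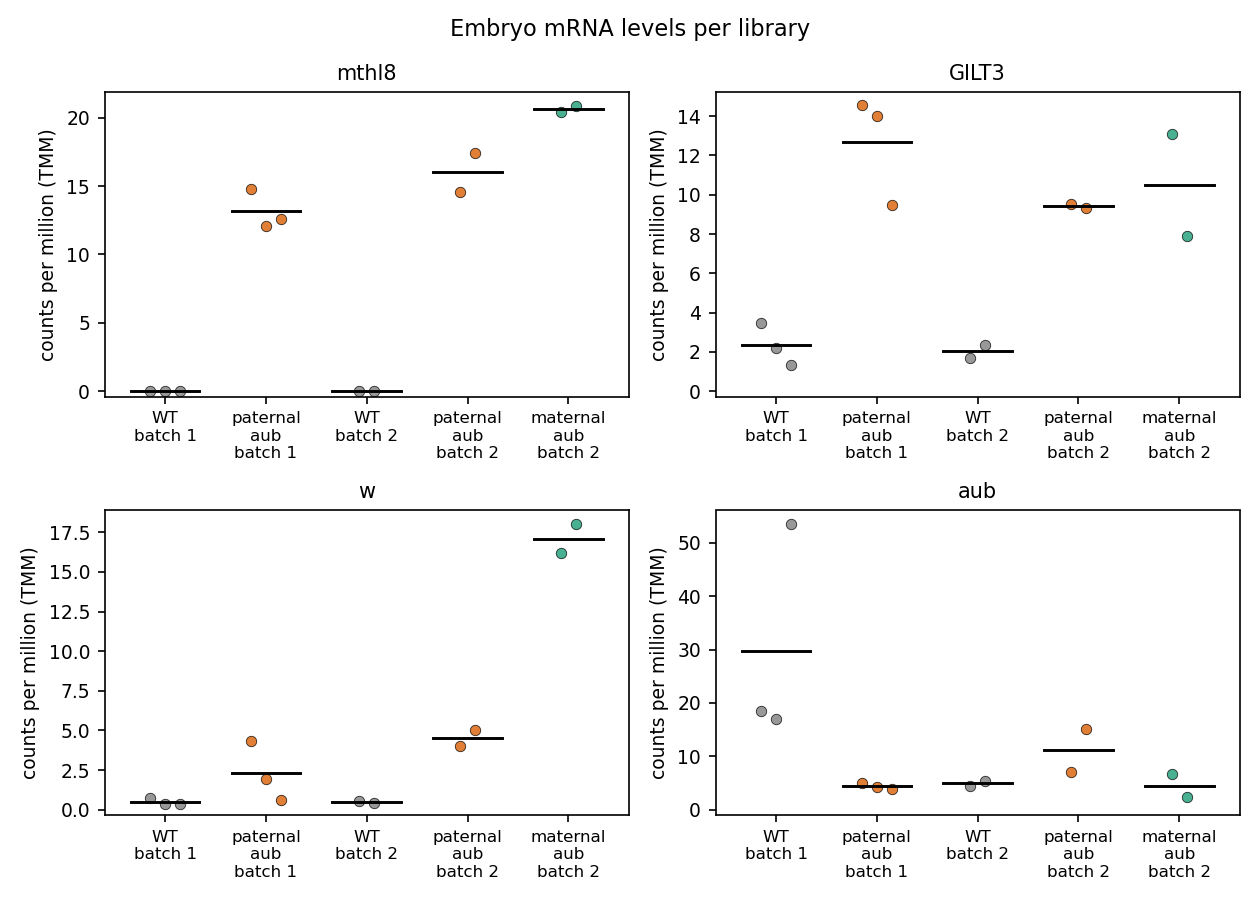
CPM of mthl8, GILT3, w and aub per embryo library (points) with group means (lines), by group and batch as the column names give it; no error bars are drawn. Paternal aub libraries averaged 14.3 CPM of mthl8 against 0 in each WT library.

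Of 20 gene lists fixed beforehand, camera called 13 in the paternal aub comparison with its preset correlation and 0 with an estimated one. The shifts of these lists depended on the batch. All 19 glycolysis genes had a positive log2 fold change (median 0.62; camera, adjusted p = 5.2e-04, and adjusted p = 0.509 with an estimated correlation). The same held for all 19 TCA cycle genes (0.50; 6.8e-04, estimated 0.509), for 37 of 42 oxidative phosphorylation genes (0.22; 0.0190, estimated 0.802), for 11 of 12 mitochondrially encoded genes (0.58; 0.0325, estimated 0.566) and for 25 of 30 late embryo and larval tissue genes (0.56; 0.0148, estimated 0.509). Hex-A measured 114 ± 47.8 against 48.2 ± 10.8 CPM (log2 fold change 1.24 ± 0.31, adjusted p = 0.127) and Ldh 259 ± 88.5 against 127 ± 57.4 CPM (1.02 ± 0.33, 0.133). Hex-A passed the threshold without WT 2-batch2 (1.35). Most maternal transcripts degraded early lay lower, with a median of -1.79 and 3 of 35 positive (2.5e-04), as did piRNA pathway genes (-1.05, 5 of 37, 6.9e-04), heterochromatin proteins (-0.84, 3 of 29, 2.1e-05) and Polycomb group genes (-0.78, 4 of 23, 6.9e-05). Further lists with a lower median were early zygotic genes (-0.58, 7 of 34, 0.00201), germ plasm and pole cells (-1.17, 3 of 19, 0.00460), dosage compensation and sex determination (-0.50, 3 of 18, 0.00700) and replication-dependent histones (-1.04, 1 of 6, 0.0148). None of the 13 calls by camera held with an estimated correlation, and fry called none. No gene of any list passed the threshold over all genes in edgeR. Adjusted over the list alone, 13 maternal transcripts, 11 heterochromatin proteins, 9 each of the piRNA pathway, Polycomb and early zygotic lists, 2 histones and 2 dosage compensation genes were lower. Adjusted over the list alone, 1 gene each of the glycolysis, late embryo, early zygotic, dosage compensation and sperm lists was higher, and of sugar sensing and insulin signalling 3 genes were higher and 1 was lower.

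Lists not called were lipid metabolism (median 0.20, 18 of 29 positive), sugar sensing and insulin signalling (0.17, 18 of 27), cytosolic ribosomal proteins (-0.02, 35 of 81), heat shock and stress (0.12, 17 of 26) and sperm and testis (0.11, 5 of 10). Innate immunity had a median of 0.23 and a mean of -0.07, and the follicle cell and eggshell list a median of 0.01, a mean of -0.23 and a downward test.

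Within batch 1 (9740 genes), the glycolysis median was 0.91 with all 19 genes positive and 9 called, TCA cycle 0.80 with 3 called, and oxidative phosphorylation 0.37. In the same batch, the maternal transcript median was -2.82 with 24 genes called lower, piRNA pathway -1.99 with 24, heterochromatin -1.47 with 17, Polycomb -1.08 with 15, early zygotic -1.12 with 15 and germ plasm -1.79 with 11. The late embryo list rose to a median of 1.01 there, with 22 of 25 genes positive and 10 called higher (camera adjusted p = 4.5e-05, 0.467 with estimated correlation). Within batch 2 (9824 genes), glycolysis lay at -0.03 with 9 of 19 positive and TCA cycle at 0.00 with 9 of 19. Oxidative phosphorylation lay at -0.06, maternal transcripts at 0.47 (29 of 33 positive), the piRNA pathway at 0.44, heterochromatin at 0.23, early zygotic genes at 0.09 and the late embryo list at -0.07. The metabolic and maternal list shifts of the pooled comparison were therefore not found in batch 2. Camera instead called maternal transcripts, the piRNA pathway and heterochromatin upward there (adjusted p = 5.3e-09, 3.0e-06 and 2.9e-04). Each was lost at 0.638 with an estimated correlation. Mitochondrially encoded genes gave 0.46 in batch 1 (camera adjusted p = 0.157) and 0.82 in batch 2 (7.5e-04, but 0.698 with estimated correlation), with 0 of 12 genes called in either batch. Batch 1 alone gave 3277 calls, among them hb (log2 fold change -4.85), zld (-2.71), vas (-3.06), Top2 (-3.70), Hex-A (1.78), Ldh (1.84), FASN1 (1.83), Ilp2 (2.29) and daw (2.05), named after their values were seen. Batch 2 alone gave 48 calls. Among 9447 genes tested in both batches, 19 of the 30 genes higher in batch 2 were also higher in batch 1 (5.04 by chance, Fisher's exact p = 1.4e-08), against 2 of 13 lower (2.12 by chance). Fisher's test takes genes as independent. Genes may vary together, so its p does not measure how a genotype difference repeats over libraries.

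**Figure D2:**
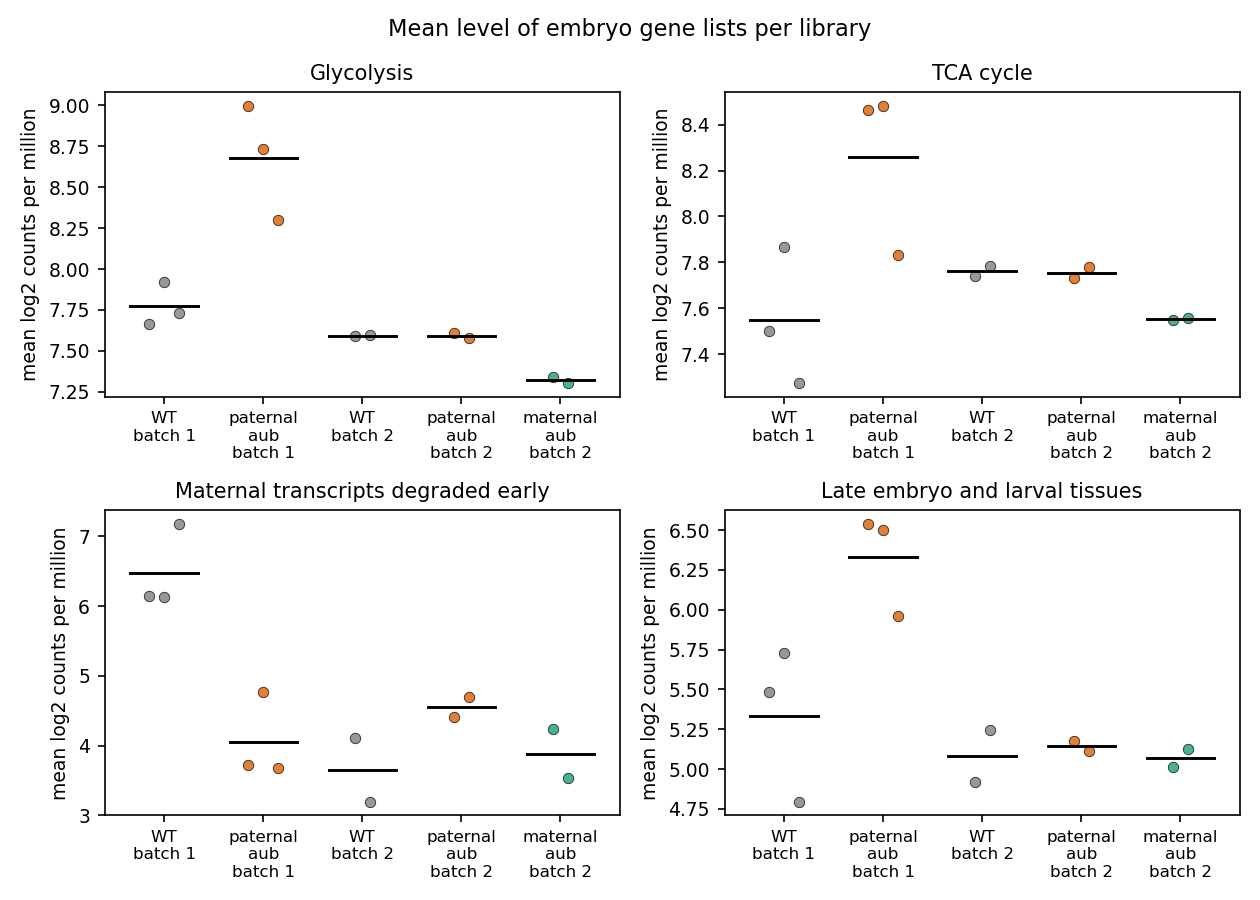
Mean log2 CPM of 4 gene lists per embryo library (points) with group means (lines) by group and batch, without error bars. Glycolysis averaged 8.68 in paternal aub and 7.77 in WT of batch 1, and 7.59 in both groups of batch 2.

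A mother's aub mutation was compared with WT in the second contrast (n = 2 against 5). The mthl8 transcript rose again, to 20.6 ± 0.308 CPM against 0, at least 24.8-fold (edgeR, adjusted p = 2.5e-04). The eye colour gene white (w; X, 2790599 to 2796466) rose from 0.474 ± 0.175 to 17.1 ± 1.25 CPM (log2 fold change 5.18 ± 0.63, 0.0105), and CG18417 from 0.237 ± 0.139 to 3.33 ± 0.0606 CPM (3.55 ± 0.51, 0.0425; chosen after its values were seen). These were the only 3 calls, against 870 genes at an unadjusted p under the threshold and 81 calls by DESeq2. The CG18417 level in WT rests on 7 counts in 5 libraries, so the size of its rise is uncertain. In paternal aub embryos w measured 3.21 ± 1.84 CPM. For all 3 genes a difference in stock background could not be separated from an effect of maternal aub. With a batch term, chosen after seeing the data, mthl8 alone passed, with w at 4.75 (adjusted p = 0.0530) and CG18417 at 3.46 (0.112). FucTC (35.3 ± 0.373 against 6.78 ± 3.47 CPM, 2.35 ± 0.39) and GILT3 (10.5 ± 3.65 CPM, 2.22) had an adjusted p of 0.124. The call of w was lost without maternal 1, maternal 2, WT 2 or WT 3 (5.05 to 5.41), that of CG18417 without any 1 of the 7 libraries (3.42 to 3.71), and that of mthl8 in no case. With only the 2 compared groups in the fit, mthl8 kept its fitted log2 fold change (10.00 against 10.18) but not its call (adjusted p = 0.637). With 0 counts in WT, that size comes from the fit and is not measured. Both maternal libraries belonged to batch 2, where all 3 genes passed, w at 5.28 and CG18417 at 3.90, among 211 calls. Values of both groups did not overlap in 1822 genes.

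Ribosomal protein genes had negative values in the maternal comparison, at a median of -0.59 with 0 of 81 positive (camera, adjusted p = 2.2e-11, estimated 0.840). Oxidative phosphorylation (-0.30, 4 of 42, 0.00270), glycolysis (-0.42, 5 of 19, 0.0403), maternal transcripts (-2.20, 6 of 35, 0.00270), Polycomb (-0.71, 0.0322), piRNA pathway (-0.97, 0.0402) and early zygotic genes (-0.86, 0.0421) were also called by camera, each with an adjusted p = 0.840 with an estimated correlation. No gene of these lists passed in edgeR, adjusted over all genes or adjusted over the list alone. Against the batch 2 WT libraries, the ribosomal median was -0.18 (3 of 81 positive), glycolysis -0.32 (2 of 19), oxidative phosphorylation -0.28 (1 of 42) and TCA cycle -0.22 (0 of 19). Maternal transcripts (0.24), the piRNA pathway (0.25), Polycomb (0.21, 19 of 23 positive) and early zygotic genes (0.14, 16 of 26) then had positive medians. Medians of lists not called ran from -1.60 for follicle cell and eggshell genes to 0.11 for sugar sensing and insulin signalling, whose mean was -0.05. The mitochondrially encoded list (median -0.05) and the sperm and testis list (-0.20) had negative medians and upward tests, and lipid metabolism (0.01) had a mean below 0. The remaining medians were -0.61 for heterochromatin, -0.10 for TCA cycle, -0.40 for heat shock (-0.32 with genes at 0 set to their bound), -0.34 for immunity, -0.30 for dosage compensation, -0.80 for histones, -0.08 for late embryo and -1.15 for germ plasm.

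Paternal and maternal aub embryos were set against each other to ask whether the parent of origin matters. The smallest p values belonged to Prx2540-2 (347 ± 19.4 against 106 ± 7.13 CPM, log2 fold change 1.71 ± 0.35), its neighbour CG11825 (72.8 ± 14.0 against 21.9 ± 0.668 CPM, 1.73 ± 0.36), CG2233 (95.6 ± 37.3 against 21.7 and 22.2 CPM, 2.12 ± 0.47), w (3.21 ± 1.84 against 17.1 ± 1.25 CPM, -2.40 ± 0.54) and CG10725 (25.0, range 4.86 to 55.6, against 1.39 ± 0.514 CPM, 4.21 ± 1.01). Each had an adjusted p of 0.682 in edgeR and did not pass. edgeR called 0 genes, against 732 at an unadjusted p under the threshold and 46 by DESeq2. In batch 2 alone (n = 2 each) edgeR called 168 genes, with 1.77 for Prx2540-2, 1.86 for CG11825, 1.84 for CG2233, -1.88 for w and 2.09 for CG10725. Values did not overlap in 21.4% of genes.

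All 19 glycolysis genes (median 0.91; camera, adjusted p = 1.6e-11), all 42 oxidative phosphorylation genes (0.56, 2.4e-11), all 81 ribosomal protein genes (0.57, 2.3e-15), all 19 TCA cycle genes (0.52, 7.6e-06), 28 of 30 late embryo genes (0.85, and 0.82 with genes at 0 set to their bound, 5.9e-04) and 18 of 26 heat shock genes (0.71, 0.0165) had higher values in paternal aub embryos. Heterochromatin proteins lay lower (-0.31, 5 of 29 positive, 0.0165). With an estimated correlation each of these had adjusted p = 0.656, or 0.811 for heterochromatin. Within batch 2, medians were 0.28 for glycolysis (14 of 19 positive), 0.26 for oxidative phosphorylation (40 of 42), 0.21 for TCA cycle (17 of 19), 0.12 for ribosomal proteins (68 of 81) and 0.12 for the late embryo list. Heterochromatin then lay at 0.01 (15 of 29, camera adjusted p = 0.765), heat shock at 0.05 (0.317) and mitochondrially encoded genes at 1.01 (10 of 12, 0.00112, and adjusted p = 0.735 with an estimated correlation). Medians of the other lists lay between -0.19 (dosage compensation) and 0.99 (follicle cell and eggshell). Median and mean differed in sign for early zygotic genes (-0.13 and 0.31), dosage compensation (mean 0.11), immunity (-0.03 and 0.51, upward test) and sperm and testis genes (-0.16 and 0.04). The histone (0.09) and germ plasm (0.03) lists had positive medians and downward tests.

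Log2 fold changes of both parents' comparisons against WT correlated across genes at r = 0.61 (covariance 0.624). Simulated counts of unchanged groups gave r = 0.38 and a covariance of 0.121 (20 simulations), a covariance difference of 0.503. Every library, WT included, was redrawn from the WT mean of each gene, with genes independent and no batch difference. In the data, the maternal transcript list averaged 6.48 mean log2 CPM in WT of batch 1 and 3.65 in WT of batch 2. Both maternal aub libraries were of batch 2. The excess thus cannot separate genotype from batch or from genes that vary together. Signs were shared by 72.6% of genes (62.7% simulated), and 2 calls were shared, mthl8 and CG18417 (0 in the simulations, 0.00145 for independent lists). With the WT libraries split between both comparisons, r averaged 0.37 (range -0.47 to 0.70 over 20 splits), the covariance 0.40, and 1 or 2 calls were shared.

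The sperm comparisons asked which small RNAs depend on piwi and on aub. In piwi sperm against WT, antisense counts rose for the telomeric retroelement TART (75.1 ± 10.7 against 12.4 ± 10.9 CPM, n = 3 each; log2 fold change 2.60 ± 0.49, edgeR adjusted p = 0.0340), Gypsy_I-int (39.4 ± 6.82 against 8.99 ± 2.01, 2.12 ± 0.27, 0.00214), DOC (125 ± 33.5 against 38.2 ± 8.85, 1.71 ± 0.29, 0.0136) and FB4_DM (54.7 ± 22.3 against 9.36 ± 1.72, 2.55 ± 0.38, 0.00704). Sense counts rose for FB4_DM (72.7 ± 26.7 against 16.2 ± 3.09, 2.17 ± 0.35, 0.0113) and for piRNA cluster3 (48.6 ± 5.14 against 10.8 ± 7.17, 2.17 ± 0.39, 0.0202). They fell for I_DM (4.86 ± 2.13 against 25.4 ± 5.17, -2.43 ± 0.34, 0.00549) and MDG1_I-int (11.1 ± 4.10 against 37.3 ± 7.19, -1.75 ± 0.33, 0.0242). Among host transcripts, exon fragments of Cyp6d5 (-3.12 ± 0.44, 0.00600) and Adgf-A (-2.57 ± 0.36, 0.00549) fell. Of snoRNAs, Or-CD9a rose (21.9 ± 1.09 against 4.22 ± 1.07, 2.40 ± 0.25, 4.6e-04) and Me28S-C3227b fell (-2.03 ± 0.32, 0.00881). In all, 97 of 10804 rows changed, 37 up and 60 down: 30 up and 58 down on the sense strand, and 7 up and 2 down on the antisense strand (1238 rows at an unadjusted p under the threshold). With 1 library left out the count was 40 to 138. Values did not overlap in 15.9% of rows, against 10% by chance for 3 against 3.

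Transposable element rows changed in both directions in piwi sperm. On the sense strand 3 of 115 rose and 5 fell, or 12 and 6 adjusted over the list alone (median 0.35; camera, adjusted p = 0.00398, estimated 0.693). On the antisense strand 5 of 125 rose and 0 fell (1238 rows of all kinds at an unadjusted p under the threshold; DESeq2 196 calls), or 6 and 1 adjusted over the list alone (median 0.05, and -0.30 scaled to miRNA counts). All 22 antisense rows of Stellate and Suppressor of Stellate had positive values (0.57, 0.00398, estimated 0.693). Also called by camera, and lost at 0.693 with an estimated correlation, were tRNA genes (-0.12, 0.00398), snoRNA genes (-0.15, 0.0274; 2 up and 2 down, or 2 and 4 adjusted over the list alone), germline elements on the sense strand (0.28, 0.0261) and accessory gland and seminal vesicle genes (-0.92, 0.0108). Lists not called, with a second value where scaling to miRNA counts turned the sign, were miRNA genes (0.26, then -0.11), gypsy-clade elements (0.49 sense, 2 down; 0.15, then -0.21, antisense, 2 up) and germline elements antisense (-0.02, mean 0.21). The others were genic piRNA sources (0.06, then -0.23), endo-siRNA hairpins (0.27, mean -0.35, then -0.04), broadly expressed miRNAs (0.22, then -0.29), testis-enriched miRNAs (1.19) and sperm and testis transcripts (-0.50). That scaling moved the median of all rows to -0.33, and its 151 calls were 27 up and 124 down. Stellate stayed at 0.30 in it, or 0.62 relative to all rows. The telomeric list had too few tested members for a test; its summed antisense level was 85.2 ± 15.3 CPM in piwi, 32.0 ± 5.26 in aub and 21.3 ± 5.03 in WT sperm, and its sense level 21.6 ± 1.06, 25.1 ± 1.96 and 7.35 ± 2.78. The calls of FB4_DM antisense, Gypsy_I-int, I_DM, Cyp6d5, Adgf-A and both snoRNAs held without any single library. Calls were lost for TART and cluster3 without WT 2, WT 3 or any piwi library (2.26 to 3.58 and 1.86 to 2.82), for DOC without piwi 1, WT 2 or WT 3 (1.46 to 1.91), for FB4_DM sense without piwi 1 or WT 3 (1.82 to 2.32), and for MDG1_I-int without piwi 2, piwi 3, WT 2 or WT 3 (-2.09 to -1.60).

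**Figure D3:**
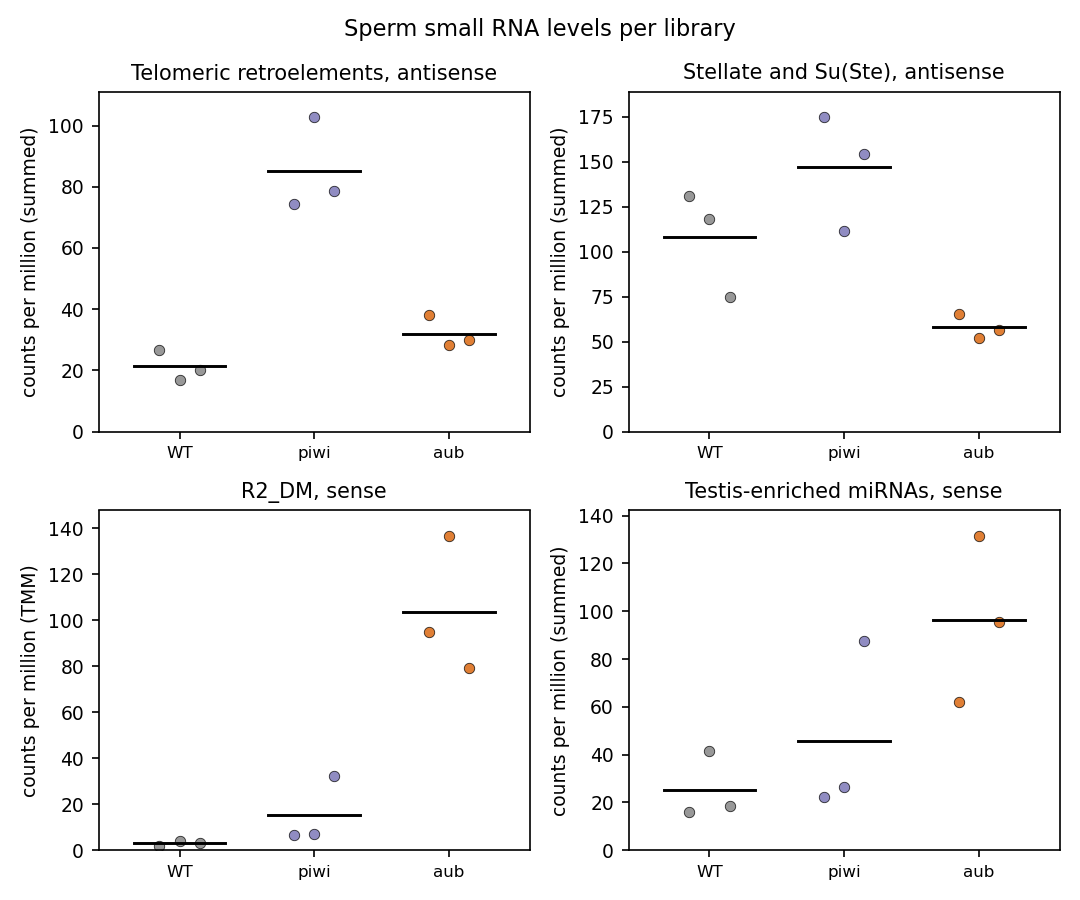
CPM per sperm library (points) with group means (lines) for telomeric antisense, Stellate and Su(Ste) antisense, R2_DM sense and testis-enriched miRNA counts, without error bars; levels are shares of counts, and list levels are sums over members. Stellate antisense averaged 147 CPM in piwi, 108 in WT and 57.9 in aub sperm.

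In aub sperm against WT, sense counts of the rDNA retrotransposons R2_DM (104 ± 29.7 against 2.93 CPM, range 1.66 to 4.05, n = 3 each; log2 fold change 5.15 ± 0.69, edgeR adjusted p = 0.00847) and R1_DM (91.5 ± 47.7 against 18.6 ± 7.29, 2.31 ± 0.46, 0.0296) rose. FB4_DM antisense rose as in piwi (35.8 ± 16.3 against 9.36 ± 1.72, 1.94 ± 0.37, 0.0244), and antisense counts of piRNA cluster93 fell (1.48 ± 1.11 against 61.4 ± 44.2, -5.35 ± 0.85, 0.0248). The testis-enriched mir-959 rose (7.95 ± 4.33 against 0.670 ± 0.595, 3.78 ± 0.80, 0.0436), as did Cp1 exon fragments (119 ± 42.6 against 32.1 ± 9.58, 1.90 ± 0.42, 0.0398). The mir-959 level in WT rests on 9 counts in 3 libraries, so the size of its rise is uncertain. Fragments of both collagen IV genes fell, vkg by a log2 fold change of -2.16 ± 0.35 (0.0115) and Col4a1 by -2.04 ± 0.35 (0.0147), as did those of Cyp6d5 (-2.19 ± 0.42, 0.0244) and snoRNA Me28S-C3227b (-2.15 ± 0.32, 0.00573). In all, 199 rows changed, 98 up and 101 down: 92 up and 89 down on the sense strand, and 6 up and 12 down on the antisense strand (1637 rows at an unadjusted p under the threshold; 21.1% without overlap). The count was 34 to 164 with 1 library left out. The R2_DM and Me28S-C3227b calls held without any single library. Those of R1_DM, mir-959 and Cp1 were lost without aub 2, aub 3 or any WT library (1.76 to 2.52, 3.20 to 4.58 and 1.57 to 2.15), and that of FB4_DM antisense without aub 2 or any WT library (1.52 to 2.21). Cluster93 and Cyp6d5 lost theirs without any aub library, WT 2 or WT 3 (-6.18 to -4.89 and -2.58 to -1.98), and vkg and Col4a1 without aub 2 or aub 3 (lowest and highest over all libraries left out -2.38 to -1.90 and -2.29 to -1.75).

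Testis-enriched miRNAs had a median log2 fold change of 2.25 in aub sperm, with 12 of 14 positive, 1 called and 8 higher adjusted over the list alone (camera, adjusted p = 6.3e-05, estimated 0.474). All 6 endo-siRNA hairpins were positive (0.86, 6.2e-04, estimated 0.474). All 22 Stellate and Suppressor of Stellate antisense rows were negative (-1.14, 1 lower adjusted over the list alone; 2.0e-06, estimated 0.866). The snoRNA genes had 13 of 228 positive, 9 called lower and 53 lower against 2 higher adjusted over the list alone (-0.74, 8.1e-28, estimated 0.474). Antisense transposable elements rose in 3 and fell in 2 of 125 rows (5 and 9 adjusted over the list alone; -0.30, but 0.24 scaled to miRNA counts; 3.3e-04, estimated 0.866), and sense elements in 6 and 6 of 115 (9 and 16; -0.24, but 0.33, not called). Further camera calls were miRNA genes (-0.57, but 0.16 scaled to miRNA counts, 9.2e-04, estimated 0.866; 8 up and 5 down adjusted over the list alone), broadly expressed miRNAs (-0.63, 2 of 28 positive, 1.0e-04, estimated 0.866) and tRNA genes (0.27, 0.0149, estimated 0.866). Not called, with the value scaled to miRNA counts where its sign turned, were gypsy-clade elements (-0.22, then 0.35, sense; 0.05 antisense with a downward test) and germline elements (0.09 sense with a mean of -0.02; -0.22, then 0.41, antisense). The others were genic piRNA sources (-0.38, then 0.17), sperm and testis transcripts (-0.06, then 0.56, and 0.14 by library size) and accessory gland genes (0.12). Scaling to miRNA counts moved the median of all rows to 0.60, against 0.18 by library size alone, and its 301 calls were 256 up and 45 down. Relative to all rows, Stellate lay at -1.05, testis-enriched miRNAs at 2.18, hairpins at 0.95, snoRNAs at -0.69 and miRNA genes at -0.44 in that scaling.

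Aub and piwi sperm were compared directly. Antisense counts were lower in aub for Gypsy_I-int (8.05 ± 1.98 against 39.4 ± 6.82 CPM, log2 fold change -2.29 ± 0.26, edgeR adjusted p = 0.00163) and DOC (40.2 ± 7.88 against 125 ± 33.5, -1.63 ± 0.28, 0.0244). The telomeric element TART_B1 measured 0.175 ± 0.0688 against 2.87 ± 1.98 CPM (-3.90 ± 0.69, 0.0263), and snoRNA Or-CD9a 3.39 ± 0.342 against 21.9 ± 1.09 (-2.68 ± 0.24, 1.6e-04). The TART_B1 level in aub rests on 5 counts, below the limit of 3 counts per library, so the size of its fold change is uncertain. The hairpin hpRNA:CR32207 was higher (2.73 ± 0.303 against 0.424 ± 0.192, 2.60 ± 0.50, 0.0351), and hpRNA:CR33940 measured 3.72 ± 1.38 against 0.128 ± 0.111 CPM from 3 counts in piwi (adjusted p = 0.00671). In all, 56 rows changed, 30 up and 26 down: 29 up and 20 down on the sense strand, and 1 up and 6 down on the antisense strand (1073 rows at an unadjusted p under the threshold; 16.9% without overlap). That count was 14 to 72 with 1 library left out. All 22 Stellate antisense rows were negative, 21 of them lower adjusted over the list alone (median -1.69; camera, adjusted p = 5.5e-17, estimated 0.369). Transposable elements fell in 3 sense and 4 antisense rows, or 21 and 10 adjusted over the list alone (-0.67 and -0.54, but 0.34 and 0.45 scaled to miRNA counts). The snoRNAs fell in 3 rows, or 21 adjusted over the list alone (-0.56, but 0.37), and testis-enriched miRNAs had 14 of 14 positive (0.97). Other medians, with the value scaled to miRNA counts where its sign turned, were -0.85 for miRNA genes (then 0.19), -0.89 for broadly expressed miRNAs (then 0.18), 0.32 for tRNAs, 0.96 for accessory gland genes and 0.53 for hairpins. Gypsy-clade elements lay at -0.71 sense (then 0.26) and -0.16 antisense (then 0.77, and 0.05 by library size), germline elements at -0.25 sense (then 0.73, and 0.05 by library size) and -0.27 antisense (then 0.62), genic piRNA sources at -0.27 (then 0.62) and sperm and testis transcripts at 0.18. All 14 camera calls, which covered every list but the last pair, were lost with an estimated correlation (adjusted p = 0.369 to 0.435 with an estimated correlation). Scaling to miRNA counts moved the median of all rows to 0.94, with 500 up and 21 down, and library size alone to 0.21, with 50 up and 20 down. Stellate stayed at -0.62 in the miRNA scaling, or -1.56 relative to all rows. Or-CD9a, Gypsy_I-int and hpRNA:CR33940 kept their calls without any single library. DOC lost it without any aub library or piwi 1 (-1.79 to -1.42), TART_B1 without the same (-4.21 to -3.26), and hpRNA:CR32207 without any 1 of the 6 (2.35 to 2.77).

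Fold changes of piwi and aub sperm against the same WT libraries correlated across rows at r = 0.66 (covariance 0.426), against r = 0.53 and a covariance of 0.127 in 20 simulations of unchanged groups, a difference of 0.299. Signs were shared by 70.3% of rows (67.8% simulated). Shared calls numbered 46, against 0.1 on average in the simulations. Of these, 13 were higher in both (0.336 for independent lists, which leave out the shared controls), among them FB4_DM on both strands and GILT3, and 33 lower in both (0.561), among them I_DM, Cyp6d5 and Adgf-A. The 3 WT libraries could not be split with 2 in each part, so part of the excess may come from the shared controls. The simulations redrew every library from the WT means with rows independent. The excess therefore also cannot separate genotype from rows that vary together.

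Class shares of all small RNA counts are given as values, since no share could pass the exact permutation test used between sperm genotypes, and no other test of shares was run. With 3 libraries per group the smallest two-sided exact permutation p is 0.1. For aub against WT it was reached by the sense miRNA, snoRNA and pseudogene shares and the antisense protein-coding share. For aub against piwi it was reached by the sense miRNA, tRNA, ncRNA and pseudogene shares and the antisense miRNA, snRNA and protein-coding shares, and for piwi against WT by the antisense miRNA and pseudogene shares. Adjusted values over 27 shares per comparison were 0.386 or more. Ribosomal RNA took 79.9 ± 1.48% of counts in WT, 81.3 ± 2.94% in piwi and 78.4 ± 1.89% in aub sperm, and miRNAs 0.941 ± 0.176%, 1.17 ± 0.253% and 0.683 ± 0.0547%. Transposable elements took 0.245 ± 0.0373%, 0.275 ± 0.0307% and 0.245 ± 0.0401% on both strands, tRNAs 5.39 ± 0.722%, 3.80 ± 0.898% and 5.59 ± 0.397%, and snoRNAs 0.591 ± 0.0143%, 0.537 ± 0.0856% and 0.435 ± 0.0425%.

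The seminal vesicle comparison asked which small RNAs the PIWI IP holds beyond total RNA (n = 4 against 2). Sense counts of the retrotransposon DOC rose from 154 ± 3.02 to 2536 ± 362 CPM (log2 fold change 4.04 ± 0.28, edgeR adjusted p = 9.4e-07), 5′ UTR fragments of mamo from 2.12 ± 1.48 to 31.6 ± 4.93 (3.94 ± 0.40, 1.4e-05) and lncRNA:iab8 from 2.87 ± 1.21 to 29.3 ± 3.95 (3.37 ± 0.33, 1.0e-05). Antisense counts rose for FW_DM (141 ± 4.31 against 37.1 ± 1.39, 1.93 ± 0.24, 6.5e-05) and I_DM (35.4 ± 4.98 against 9.55 ± 0.209, 1.89 ± 0.26, 1.8e-04). The snoRNAs lola-c (3.45 ± 0.886 against 79.2 ± 0.106, -4.55 ± 0.26, 6.7e-07) and lola-d (2.97 ± 1.05 against 66.0 ± 4.93, -4.51 ± 0.30, 8.2e-07) fell. These 7 calls held in each alternative and without any single library. In all, 3435 of 18666 rows changed, 1569 up and 1866 down: 1229 up and 1812 down on the sense strand, and 340 up and 54 down on the antisense strand (6001 rows at an unadjusted p under the threshold; 45.0% without overlap). The count fell to 1533 without total RNA 1 and to 1407 without total RNA 2.

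Transposable elements rose in the IP on both strands. On the sense strand 88 of 179 rose and 2 fell (median log2 fold change 1.50, or 1.44 with rows at 0 set to their bound; 108 and 3 adjusted over the list alone), and on the antisense strand 92 of 182 rose and 1 fell (1.33, or 1.29; 116 and 1 adjusted over the list alone). The list tests held with an estimated correlation for both (camera, adjusted p = 0.0430 and 0.00695), for gypsy-clade elements sense (9 of 26 rose, 0.94, estimated 0.0391) and antisense (12 of 28, 1.12, 0.0263), for germline elements antisense (11 of 20, 1.15, 0.0430) and for snoRNA genes, of which 237 of 250 fell (-2.78, 0.0122). Calls of camera not held were tRNA genes (151 of 273 fell, -2.22; adjusted p = 0.188 with an estimated correlation), miRNA genes (55 of 147 fell, -0.89, but 1.14 by library size alone, estimated 0.124), broadly expressed miRNAs (16 of 29 fell, -0.72, but 1.32 by library size and 0.03 scaled to miRNA counts, 0.124), germline elements sense (13 of 22 rose, 1.45, 0.124), sperm and testis transcripts (8 of 45 rose, 0.92, 0.277) and Stellate antisense (0 of 21 passed, 0.69, 0.582; 6001 rows of all kinds had an unadjusted p under the threshold and DESeq2 called 3200). Not called were Stellate sense (0.80), genic piRNA sources (0.30), hairpins (0.10), testis-enriched miRNAs (0.15), accessory gland genes (0.36) and Y-linked fertility genes (0.54). The TMM factors were 0.356 and 0.427 in total RNA against 1.02 to 2.11 in the IP. Summed on total counts, snoRNA genes stood at 6721 ± 2095 CPM in the IP and 8380 ± 282 in total RNA. The tRNA genes stood at 7609 ± 1413 and 9591 ± 1324 CPM. The size of the snoRNA and tRNA falls thus depends on the scaling.

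As shares of all counts, transposable elements took 0.969 ± 0.302% sense and 0.387 ± 0.121% antisense in the IP, against 0.0634% and 0.0406% in total RNA. Without the 5 largest features these were 3.55 ± 0.381% and 1.42 ± 0.137% against 0.615% and 0.394%, a smaller ratio on both strands. The miRNA share was higher in the IP (15.2 ± 4.64% against 6.00 ± 1.01%), but not without the 5 largest features (40.9 ± 4.14% against 41.8 ± 1.07%). The miRNA median fold change was -0.89 with TMM scaling, -0.16 with miRNA scaling and 1.14 by library size alone. Library size alone moved the median of all rows to 2.08 and gave 11644 up and 169 down, and miRNA scaling moved it to 0.83 and gave 4336 up and 841 down. Relative to all rows, miRNAs lay at -0.95 and -0.99, sense transposable elements at 1.47 and 1.43 and snoRNAs at -2.80 and -2.89 in these scalings. Ribosomal RNA took 68.1 ± 7.5% of IP counts and 86.5% of total RNA counts.

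**Figure D4:**
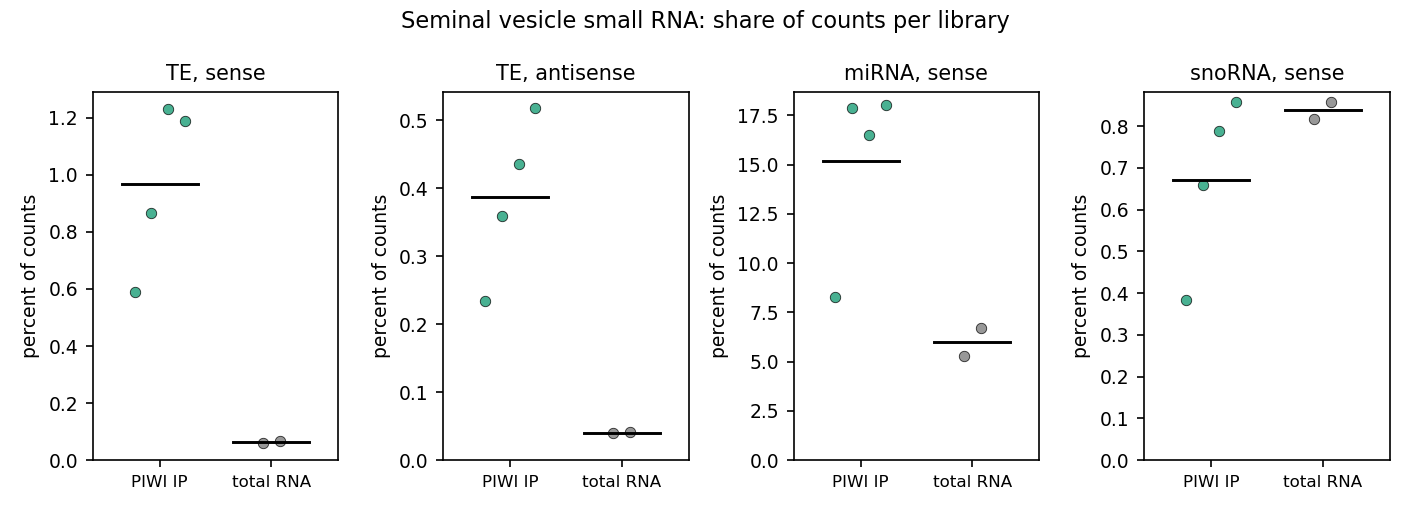
Percent of all counts per seminal vesicle library (points) with group means (lines) for sense and antisense transposable elements (TE), miRNAs and snoRNAs, without error bars. The TE sense share averaged 0.969% in PIWI IP and 0.0634% in total RNA, and miRNA took 15.2% and 6.00%.

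WT sperm was compared with WT testis to ask which testis small RNAs sperm retains (3 libraries against 1 per testis group, with the spread taken from sperm). Testis libraries were prepared in a reduced reaction volume and sperm libraries were not, so tissue and preparation could not be told apart. The piRNA cluster flam fell from 2010 ± 1379 CPM in testis to 20.3 ± 2.03 in sperm (sense; log2 fold change -6.36 ± 0.63, edgeR adjusted p = 2.0e-05), GTWIN_I-int antisense from 111 ± 79.9 to 0.679 ± 0.457 (-6.99 ± 0.63, 1.9e-05) and mir-959 from 191 ± 51.4 to 0.565 ± 0.458 (-8.43 ± 0.72, 1.9e-05). The sperm levels of GTWIN_I-int and mir-959 rest on 13 and 9 counts, so the sizes of these falls are uncertain. Fragments of regucalcin rose from 1.95 ± 0.779 to 98.2 ± 34.6 CPM (5.73 ± 0.56, 2.0e-05). Seminal fluid gene fragments of Acp36DE (68.8 ± 48.2 CPM in sperm) and Mst57Db (45.9 ± 40.8 CPM) also rose, from a single count each in testis. The 3′ UTR of Mst84Dd (116 ± 17.9 CPM in testis) and that of tj (54.1 ± 39.7 CPM) fell to 2 counts and 1 count in sperm. Small RNA of aub fell (-4.00, adjusted p = 0.00569), and that of piwi did not pass (-3.16, 0.0808). In all, 7840 of 13723 rows changed, 3628 up and 4212 down: 3472 up and 3671 down were sense rows, and 541 of the rows down were antisense (8592 rows at an unadjusted p under the threshold; 63.1% without overlap). With testis as 1 group of 3 libraries the count was 4918, 4778 of them shared.

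Most rows of the lists typical of testis fell in sperm. Stellate and Suppressor of Stellate fell in 40 of 40 antisense rows (median -5.71) and 42 of 43 sense rows (-6.03, or -5.59 with rows at 0 set to their bound), testis-enriched miRNAs in 20 of 20 (-6.89, or -6.68), hairpins in 8 of 8 (-5.14, or -3.77), and sperm and testis transcripts in 48 of 51 (-5.75, or -5.24). Transposable elements fell in 142 of 169 sense rows (-3.54) and 160 of 170 antisense rows (-4.73), of which 2 rose. Gypsy-clade elements fell in 18 of 24 and 28 of 28 rows, germline elements in 17 of 21 and 19 of 19, Y-linked fertility genes in 7 of 8 (-4.90, or -4.22), miRNA genes in 68 of 111 with 7 up (-1.98), and snoRNAs in 120 of 240 with 14 up (-1.17, but 0.35 scaled to miRNA counts). Accessory gland and seminal vesicle genes rose in 29 of 32 (7.02, or 3.35 with the 20 genes at 0 in testis set to their bound), and tRNA genes rose in 77 and fell in 24 of 257 (0.38). Broadly expressed miRNAs (-0.89, but 0.33 scaled to miRNA counts, 2 up and 12 down) and genic piRNA sources (median 0.20, mean -1.36, 7 up and 6 down) were not called by camera. None of the 16 camera calls held with an estimated correlation (adjusted p = 0.248 to 0.783 with an estimated correlation), and fry called 14. Scaling moved the median of all rows from 0.21 to 0.50 by library size and to 1.78 by miRNA counts, which gave 6790 up and 2474 down. In the latter, the Stellate (-4.30 antisense), transposable element (-3.23 antisense) and testis-enriched miRNA (-5.11) medians stayed negative.

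The testis groups T1, T2 and T3 had 1 library each, so their differences have no replicate check and no test. The antisense share of counts was 8.68% in T1 (95% Clopper-Pearson interval 8.65 to 8.71), 5.66% in T2 (5.64 to 5.68) and 1.92% in T3 (1.91 to 1.93), against 0.610 ± 0.0922% in WT sperm. Transposable elements took 10.0% (9.99 to 10.0), 6.22% (6.20 to 6.24) and 1.83% (1.82 to 1.84), against 0.245%. Without the 5 largest features the antisense shares were 31.0%, 24.0% and 13.1%, against 3.28% in sperm, and the transposable element shares 35.7%, 26.4% and 12.5%, against 1.32%. Stellate antisense levels were 9066 (8971 to 9162), 6649 (6565 to 6732) and 2007 (1972 to 2043) CPM, against 108 ± 29.4 in WT sperm. Testis-enriched miRNAs measured 3514 (3455 to 3574), 3287 (3228 to 3346) and 1053 (1027 to 1079) CPM, against 25.3 ± 14.0. The piRNA cluster sense share was 7.47%, 7.13% and 6.44% (7.44 to 7.49, 7.10 to 7.15 and 6.42 to 6.46), and 6.12%, 4.62% and 2.17% without the 5 largest features, which include cluster92. Ribosomal RNA took 66.1% (66.0 to 66.1), 70.2% (70.2 to 70.3) and 79.2% (79.2 to 79.3) of counts.

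**Figure D5:**
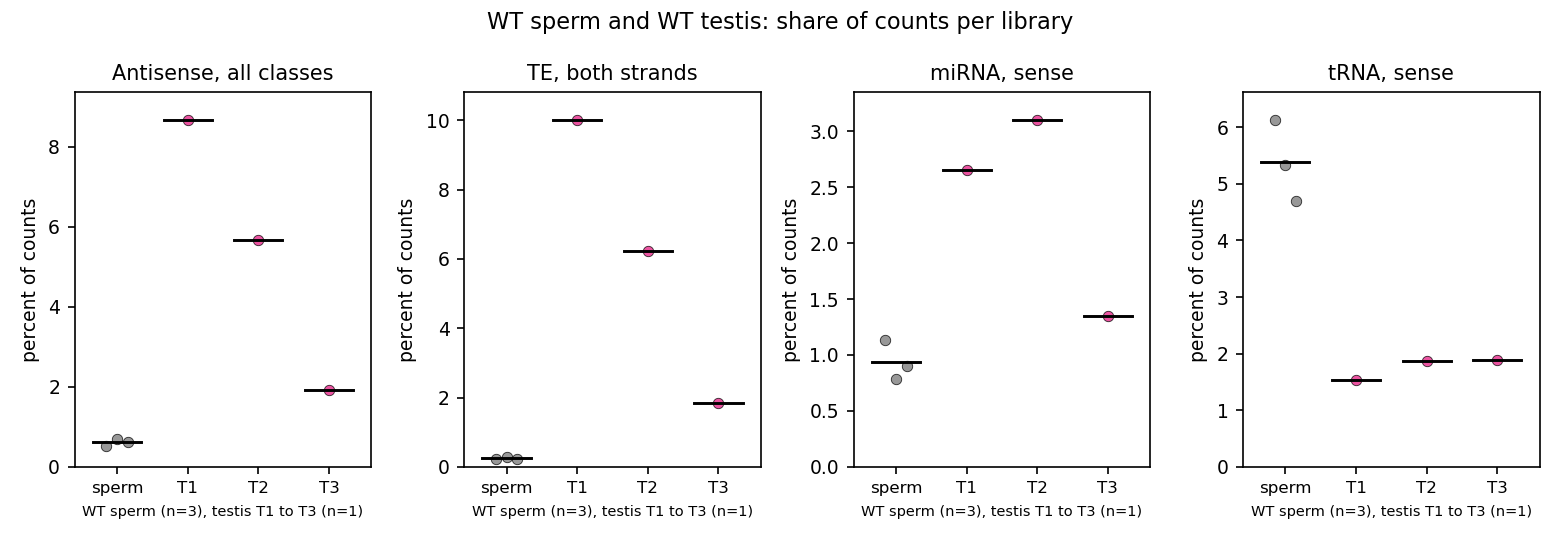
Percent of all counts on the antisense strand, on transposable elements (TE), miRNAs and tRNAs in 3 WT sperm libraries (points, line at the mean) and in 1 testis library each of T1, T2 and T3, without error bars. The antisense share was 8.68% in T1, 5.66% in T2, 1.92% in T3 and 0.610% on average in sperm.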

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

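All tests of explanations in this part were chosen after the results were seen. Dixon's ratio was examined for 88 measures in the groups of 4 or 5 libraries, which were paternal aub embryos, WT embryos and PIWI IP. In 7 of these a library lay far from the others, and chance flags about 1 in 20 measures (4.4 here). The smaller groups, which include all sperm, maternal aub, total RNA and testis groups, were not examined in this way. Paternal aub 2-batch2 had 16289732 assigned counts against 4634192 to 7926235 in the other paternal libraries (ratio 0.718), and 15.1 CPM of aub against 3.95 to 7.08 (0.720). WT 3 had 53.5 CPM of aub against 4.49 to 18.5 (0.714), 32.9 CPM of CG11825 against 65.5 to 76.2 (0.753) and 43.2 CPM of CG2233 against 90.6 to 107 (0.744). WT 1-batch2 had 0 CPM of CG18417 against 0.247 to 0.345 (0.715), a difference of very few counts. PIWI IP 1 had 8.29% miRNA against at least 16.5% in the other IP libraries (0.843). WT 3 and paternal aub 2-batch2 account for 5 of the 7, and no explanation of these was tested.

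Of the 5 genes higher in paternal aub than in WT embryos, mthl8 and CG18417 kept their calls in 3 further fits. These had the early zygotic covariate, the maternal transcript covariate, or batch 2 alone (lowest log2 fold change 4.18). Both genes were grouped by that outcome. Like the maternal covariate, the early zygotic one varied within groups mostly between the WT batches (3.66 and 2.09 mean log2 CPM). The 3 fits therefore do not decide on stage. The mthl8 gene had 0 counts in WT libraries whose maternal transcript level ran from 3.20 to 7.17. All paternal aub libraries lay within that range (3.68 to 4.77). That argues against a stage difference that maternal transcripts follow as the whole cause for mthl8. For CG18417, whose WT level rests on 7 counts, it stays open. With the maternal covariate GILT3, CG42825 and CG4835 went from 2.33 ± 0.32, 3.42 ± 0.48 and 2.13 ± 0.32 to 2.32 ± 0.35, 3.39 ± 0.57 and 1.97 ± 0.33, but with larger SEs all 3 calls ended (edgeR adjusted p from 0.0694 to 0.0846). This covariate varied within groups mostly between the WT batches (6.48 and 3.65 mean log2 CPM), so the fit alone does not decide on stage. All 3 genes were higher in both batches, while the maternal transcript median was -2.82 in batch 1 and 0.47 in batch 2. The 3 genes were called in a fit of the same libraries without a batch term, which favours genes of like sign in both batches. Their like signs therefore do not decide on a stage difference that maternal transcripts follow. CG42825 and CG4835 had lower values in batch 2 (2.32 and 1.22) than in batch 1 (3.74 and 2.72), so for these a stage difference that late genes follow stays open. A difference in the genetic background of the stocks could not be separated from a true effect of parental aub for any of the 5, nor for w of maternal aub embryos. GILT3 small RNA also rose in piwi sperm, where aub is not the mutated gene (log2 fold change 4.11, edgeR adjusted p = 9.6e-05). Small RNA of w had 2 counts in WT, 8 in piwi and 25 in aub sperm. The paternal aub grouping gave 6 calls, and 7 of 100 groupings of the same libraries (126 possible) gave as many; the highest, with 2381 calls, joined paternal 1 and 2 with WT 1, 2 and 3, which is nearly all of batch 1.

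Glycolysis and TCA cycle genes were weighed next. With the maternal transcript list as a covariate, the glycolysis median was 0.58 against 0.62 without it. This does not decide on a stage difference, since the covariate varied within groups mostly between the WT batches (6.48 and 3.65 mean log2 CPM). In batch 1, where glycolysis genes were higher, maternal transcripts lay lower (median -2.82). With a batch term the glycolysis median was 0.55, which decides nothing, since the groups are balanced over the batches. The late embryo list stood at 6.33 against 5.34 mean log2 CPM in batch 1 and 5.15 against 5.08 in batch 2, so a stage difference that late genes follow stays open. In batch 2 alone the glycolysis median was -0.0287 (SD between genes 0.137) against 0.91 in batch 1, which argues against a paternal effect of like size in both batches. A difference confined to the batch 1 collections, technical or biological, stays open.

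The R1_DM and R2_DM rise in aub sperm was the third pattern. The rRNA counts per other count stood at 0.917 of their WT value in aub (1.06 from the highest aub to the lowest WT library), while R1_DM rose 4.97-fold and R2_DM 35.6-fold. That argues against a general rise of rRNA fragments as the whole cause. A change in few rRNA fragments would hardly move this total, which took 78.4% of aub counts, and was not tested. A stock difference in rDNA insertions was not tested and stays open beside an effect of aub. For piwi against WT, aub against WT, aub against piwi, and sperm against testis as 1 group, the real grouping was the 1 of 10 with the most calls (97, 199, 56 and 4918; the highest other gave 0 in each), and 10 groupings are too few for a share under 0.05.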

How the results depend on the processing

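In paternal aub against WT (6 calls), size factors and no filter kept the count. DESeq2 gave 883 (234 up, 649 down; 6 shared), a replicate block 3173, the 2 groups alone 2, an early zygotic covariate 2, a maternal transcript covariate 2, a batch term 33 (23 up, 10 down), batch 1 alone 3277 (1623 up, 1654 down) and batch 2 alone 48 (34 up, 14 down). Leaving out 1 library gave 2 to 734: 734 without WT 2-batch2, 228 without WT 1-batch2, 3 without WT 1, and 2 without paternal 1, paternal 2, WT 2 or WT 3. In maternal aub against WT (3), DESeq2 gave 81 (10 up, 71 down), a block 3697, 2 groups 1, the maternal covariate 1, a batch term 1 and batch 2 alone 211 (79 up, 132 down). Leaving out 1 library gave 1 to 3: 1 without maternal 1, maternal 2, WT 2 or WT 3, and 2 without WT 1 or WT 1-batch2. In paternal against maternal aub (0), DESeq2 gave 46, a block 3004, batch 2 alone 168 (112 up, 56 down) and the rest 0, as did each library left out. These 3 blocks held only libraries whose replicate number both groups shared. Their counts thus also reflect fewer libraries and, where maternal libraries entered, batch.

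In piwi against WT sperm (97), DESeq2 gave 196 (77 up, 119 down), no filter 367 (153 up, 214 down), 2 groups 61, miRNA scaling 151, library size 102 (35 up, 67 down) and a block 120. Leaving out 1 library gave 40 to 138: 40 without piwi 1, 41 without piwi 2, 51 without piwi 3, 44 without WT 2, 47 without WT 3. In aub against WT (199), DESeq2 gave 389 (186 up, 203 down), no filter 648 (361 up, 287 down), miRNA scaling 301, library size 166 (98 up, 68 down) and a block 304 (153 up, 151 down). Leaving out 1 library gave 34 to 164: 34 without aub 2 or aub 3, 63 without WT 2 and 70 without WT 3. In aub against piwi (56), DESeq2 gave 144 (64 up, 80 down), no filter 320, 2 groups 103, strands apart 84 (39 up, 45 down), miRNA scaling 521 and a block 86 (40 up, 46 down). Leaving out 1 library gave 14 to 72: 14 without aub 3, 20 without aub 2, 28 without aub 1, 24 without piwi 1 and 26 without piwi 2.

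In the seminal vesicle (3435), library size gave 11813, miRNA scaling 5177 and a block 4652, and leaving out 1 library 1407 to 4731. The others stayed within 1.5 times. In sperm against testis (7840), DESeq2 gave 4164 (1095 up, 3069 down), testis as 1 group 4918 (2116 up, 2802 down), and leaving out 1 library 5976 to 7676. No paired analysis was possible because the columns do not give the replicate number of a testis library. The 3 testis comparisons and their alternatives were not run, with 1 library per group.

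Calls of gene lists went from 13, 7 and 7 in the embryo comparisons, 6, 8 and 14 in sperm and 16 in sperm against testis to 0 each with an estimated correlation, and from 12 to 6 in the vesicle. With a batch term the embryo counts were 13, 4 and 13. The snoRNA share difference of piwi against WT sperm reversed without the 5 largest features (0.0671 against -0.0534 points), and that of rRNA ran from -0.183 (without piwi 1) to 2.67 points with 1 library left out (1.45 with all). Named genes that reversed were aub (1.18), piwi (0.63) and Ldh (-0.0949) of paternal aub in batch 2 alone, and piwi of maternal aub with the maternal covariate (0.0472) and in batch 2 alone (0.24). In paternal aub, mthl8 and CG18417 passed under every alternative, with adjusted p from 5.1e-15 to 0.0355. In maternal aub, mthl8 passed under 8 of 9, with fitted log2 fold changes from 8.89 to 10.47. With 0 counts in WT, these sizes come from the fit and are not measured. The mthl8 gene did not pass with only the 2 compared groups in the fit (10.00, adjusted p = 0.637). The 7 named vesicle genes and 8 named genes of sperm against testis passed throughout; aub and piwi small RNA of that comparison were not rerun. Of 200 values of the 10 paternal genes, 147 kept direction and side of the threshold, 39 were weaker, 11 stronger and 3 reversed. Of 180 piwi sperm values 157 held and 23 were weaker, of 150 aub values 112 and 38, and of 90 aub against piwi values 73 and 17.

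Except for fewer libraries, the cause was not tested. Replicate numbers did not pair libraries: same-number correlations were -0.06 to 0.04 for paternal aub, -0.07 to 0.16 for piwi, -0.03 to 0.15 for aub and -0.05 to 0.15 for aub against piwi, and 0 of 6, 4 of 6, 4 of 6 and 3 of 6 libraries correlated best with their own number. Comparisons with 2 pairs gave 0.10 (maternal), -0.14 (paternal against maternal) and 0.19 (vesicle). The block moved the count by over 1.5 times in the 3 embryo comparisons and in aub against WT and against piwi, but not in piwi against WT or the vesicle. In embryos, the block fit held only libraries of a shared number. These were paternal and WT 1 to 3, maternal and WT 1 and 2, and paternal and maternal 1 and 2. Those paternal and WT libraries were of batch 1 and the maternal ones of batch 2. Their counts therefore do not show what the block itself does. Depth limits most the WT library with 1690431 counts and all antisense rows.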

Other observations

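All tests named here were chosen after the results were seen. The mthl8 gene is the first from the left end of chromosome arm 3L in the reference. Its next neighbours did not pass the threshold in paternal aub embryos, in a fit that recovers few 2-fold changes: CG43149 (53873 to 54751) had a log2 fold change of 0.81 (adjusted p = 0.257) and Lsp1gamma -0.90 (0.140). In sperm small RNA, mthl8 had 0 counts in WT, 22 in piwi (1.04 ± 0.111 CPM) and 32 in aub sperm (1.25 ± 0.440 CPM). GILT3 had 22 counts in WT (1.16 ± 0.525 CPM), 498 in piwi (24.4 ± 7.09 CPM) and 1092 in aub (40.6 ± 9.95 CPM), and w had 2, 8 and 25. CG42825 had 11, 2 and 0 counts, CG4835 1, 0 and 0, CG18417 2, 0 and 0, and neo 1, 1 and 0. Of the genes that rose in aub embryos, mthl8, w and GILT3 thus had more sperm small RNA counts in both mutants than in WT, of which GILT3 alone was tested.

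For Stellate, summed sense counts were 4.84 ± 1.04 CPM in WT, 19.8 ± 5.11 in piwi and 11.2 ± 1.63 in aub sperm, while antisense counts were 108 ± 29.4, 147 ± 32.4 and 57.9 ± 6.65 CPM. Hairpin counts were 61.9 ± 2.59, 99.9 ± 9.26 and 118 ± 2.35 CPM, and 3151, 2974 and 830 CPM in T1, T2 and T3. In seminal vesicle, Stellate antisense measured 49.3 CPM in PIWI IP and 8.61 in total RNA. These are shares of counts, summed over members and not tested.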
